A study of Mus musculus with 2 samples.

How the data were processed

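The study measured gene expression in mouse urogenital sinus mesenchyme (UGM) cells, the fetal stromal cells that surround the urogenital sinus epithelium from which the prostate buds. The cells came from male C57BL/6 mice at day 16, per the labels. They were kept in RPMI medium with 5% charcoal-stripped serum, which is depleted of steroids, and 5 µg/ml Plasmocin, an antibiotic. The treated culture also received testosterone (12 nM) and estradiol-17β (120 pM), abbreviated T+E2. There was 1 array of untreated cells and 1 array of T+E2 cells. The sample titles carry a time of 24 h, whereas the treatment protocol, the descriptions and the characteristics all give 72 h, and 72 h is used here. The descriptions differ in how dense the cells were before treatment: confluent for the untreated cells and nearly confluent for the T+E2 cells. The growth protocol instead gives the same density, short of confluence, for both, and the conflict is not settled here.

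Total RNA was extracted with an Omega Bio-Tek kit and biotinylated cDNA was made with NuGEN kits, per the labels' protocols. The arrays were Affymetrix mouse expression arrays with 45101 probe sets. GCRMA, which corrects the background by probe sequence, quantile-normalizes the arrays and summarises the probes of a probe set, is the method named in the submitters' processing notes; its version is not given in the sources used here. The deposited values are GCRMA intensity values on a linear scale, from 3.82 to 67555 on the untreated array and from 3.75 to 71889 on the T+E2 array. Under GCRMA most probe sets without signal collapse to a low value, and 50.3% of probe sets on the untreated array and 52.0% on the T+E2 array lay under an intensity of 8.

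Here the log2 of each intensity was taken, with no further scaling. A floor of 5 on the log2 scale (intensity 32) was applied to both arrays before a difference was formed, so that differences among background values did not count. Differences are T+E2 minus untreated. A gene was called measured when at least 1 array reached the floor. Where only 1 array reached it, the fold is a lower bound against the floor and is written as "at least". Genes at least 2-fold higher or lower (log2 difference of 1 or more, or of -1 or less) were counted. With 1 array per group there is no replicate check of any difference, no p-value was computed, and the number of arrays limits the precision of every value.

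Probe sets were named from the platform's annotation, which can hold older symbols, with symbols updated through the gene identifiers of the RefSeq gene table of assembly GRCm38.p6. That table was used for names, RNA class and genomic span (the length of the gene from first to last base), and no coordinates are given. Of the 45101 probe sets, 64 were the manufacturer's controls, 34945 named 1 gene, 932 named several genes and 9160 were not listed. The probe sets with 1 gene stood for 18193 genes, 18145 of them in the RefSeq table. The probe set with the highest mean over both arrays gave the gene's value. Probe sets that named several genes were left out of the gene counts.

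Before the data were examined, 37 gene lists were fixed: 28 of pathways and gene classes and 9 of cell type markers. For each list with at least 5 measured members (29 lists), the median log2 difference was placed among the medians of 10000 random lists of the same size, matched on mean level in 20 bins. A list was said to stand apart when its median lay below the 2.5th percentile or equally far out in the upper tail, and by chance 1.45 of 29 lists would do so. This describes these 2 arrays and is not a test across cultures. A second matching, on level in 10 bins and genomic span in 5 bins, was added after a trend with genomic span had been seen.

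The genes named in the text were chosen by a rule fixed before the data were examined. It takes the 10 largest differences in each direction among genes at or above the floor on both arrays, and up to 5 genes in each direction at 7 or more (log2) on 1 array and under the floor on the other. Both parts leave out genes whose probe sets lay on opposite sides and symbols that are only clone or locus numbers. It also takes, from each list, up to 4 members at least 2-fold different, or the 2 largest where there were none, and a set of steroid receptors and enzymes. Srd5a1, Srd5a2 and Cyp19a1 belong to that set and are not analysed here, since no probe set carried these names alone. Genes outside the rule are named as chosen after their values were seen.

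The 2-fold count was tested on simulated arrays with 10267 measured genes. Noise with an SD of 0.12 was added to each array, near the SD of the hybridization spike differences between the arrays (0.121). The count recovered 50 of 50 genes at a true log2 change of -2, 49 of 50 at -1.3, 47 of 50 at 1.3 and 50 of 50 at 2, and called 0 of 10067 unchanged genes. The lists were tested on separate simulated differences, with a small trend with level and a spread close to the SD of 0.62 across measured genes. Of 1000 random lists with no shift, 33 stood apart (3.3%), and of 40 lists shifted by 0.4, 31 stood apart (77.5%). The noise of 0.12 is smaller than the spread between cultures would be, and neither simulation draws on replicate cultures, so these figures test the calculation only.

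Alternatives covered other floors, no floor, other fold thresholds, centring on the median difference, loess on the mean level, a second quantile normalization, other rules for the gene value, unmatched random lists and list means. Without a floor, genes under it on both arrays also entered, so list medians then rest partly on background values. Those added after the data had been seen were loess on genomic span, protein-coding genes alone, the matching on span, and lists without members shared with the immediate early genes. Lists of delayed growth response genes and of corticosteroid response genes were written after some of their members' values had been seen, and are used only after the main results. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.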

Results

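Gene expression was compared between UGM cells cultured for 72 h in steroid-depleted medium and UGM cells given testosterone (12 nM) and estradiol (120 pM) in the same medium, with 1 array for each condition. The series set out to find genes induced by the 2 hormones in this mesenchyme. Of 45101 probe sets, 42.9% reached the floor (log2 of 5) on the untreated array and 42.1% on the T+E2 array, and the median intensities were 7.60 and 6.12. Of 18193 named genes, 10267 were measured. These comprised 10009 measured on both arrays, 165 only with T+E2 and 93 only in untreated cells. There were no replicates, so every value below is a difference between 2 arrays and cannot be set against the spread between cultures.

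Fos, which encodes a subunit of the AP-1 transcription factor, showed the largest difference among all genes measured on both arrays, at an intensity of 315 in untreated cells and 10620 with T+E2 (33.7-fold, log2 difference 5.07). Fam107a followed at 31.9-fold, with 3 probe sets on the same side, and then the immediate early gene Ier2 at 19.0-fold. The sulfotransferase gene Sult1a1 was 9.64-fold higher with T+E2. Zfp36, which encodes an mRNA decay factor, was 8.76-fold higher, and Fkbp5, a steroid-responsive co-chaperone of steroid receptors, was 7.95-fold higher. The other genes among the 10 largest were Itgbl1 (7.31-fold), the microtubule-associated protein gene Map1b (6.87-fold), Depp1 (6.29-fold) and Armcx4 (6.26-fold).

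Among genes lower with T+E2 that were measured on both arrays, with agreeing probe sets and symbols other than clone or locus numbers, Phxr4 differed most, at 519 in untreated cells and 53.9 with T+E2 (log2 difference -3.27). Next came Mir99ahg (-2.47), the zinc finger gene Zfp40 (-2.47), Particl (-2.30) and Kcnq1ot1 (-2.29), the imprinted antisense RNA of the Kcnq1 locus, whose 3 probe sets lay on the same side. Gpm6b (-2.24), Mlana (-2.22), Mpp4 (-2.17), the neuropeptide gene Npff (-2.16) and Rab26os (-2.10) completed the 10. Phxr4, Mir99ahg, Particl, Kcnq1ot1 and Rab26os are long non-coding RNAs in the RefSeq table.

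Some genes reached the floor on 1 array only. Lcn2, which encodes the iron-siderophore carrier lipocalin 2, was at least 17.2-fold higher with T+E2. Eppk1 was at least 14.9-fold higher, and Zbtb16, which encodes the transcription factor PLZF, at least 14.7-fold higher, the latter with 2 probe sets on the same side. The early growth response gene Egr3 was at least 11.5-fold higher and Ccbe1 at least 7.97-fold higher. In the other direction, 4 genes met the rule. Nat8f3 was at least 6.78-fold lower with T+E2, Wdr38 at least 6.25-fold lower, the chemokine gene Cxcl15 at least 5.92-fold lower and Ttyh1 at least 5.40-fold lower.

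Across the 10267 measured genes, 509 (4.96%) were at least 2-fold higher with T+E2, 412 (4.01%) were at least 2-fold lower and 9346 lay between. At 4-fold or more, 45 genes were higher and 36 lower. The median log2 difference was 0.07 (interquartile range -0.32 to 0.45), with an SD of 0.62 across genes, and the log2 levels of measured genes correlated across genes at 0.958. The 18 hybridization spike probe sets, added to both samples, differed by -0.25 to 0.09 (log2). Among 4537 genes with more than 1 measured probe set, all probe sets lay on the same side in 3149 (69.4%), and the median SD between probe sets of a gene was 0.22. Among the 299 of these genes that were at least 2-fold different, 262 (87.6%) had all probe sets on the same side. With a trend of the difference with genomic span removed, 303 genes were higher and 433 lower, and with centring on the median difference 408 and 520, so the larger count lay on the lower side.

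**Figure D1:**
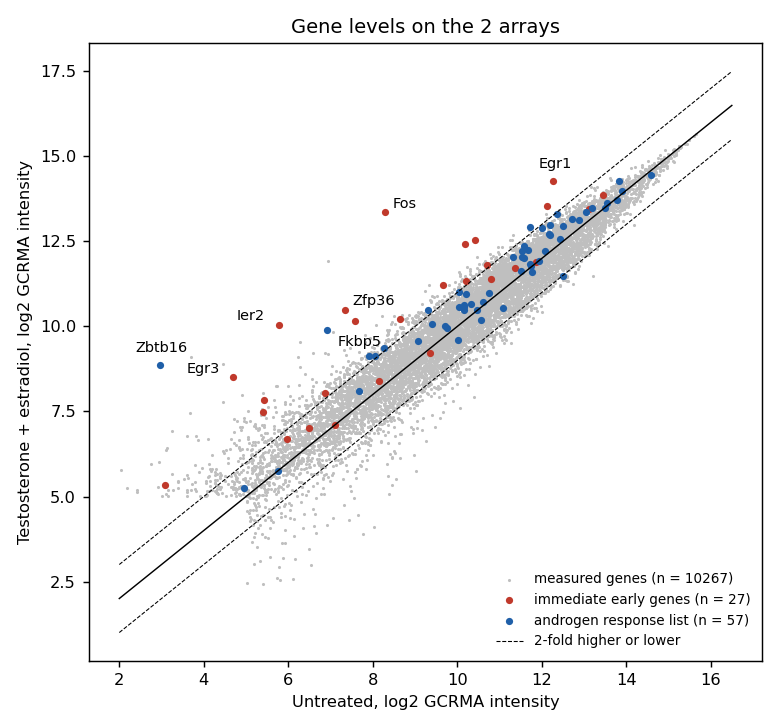
Level of each of the 10267 measured genes on the untreated array (x axis, log2 intensity) and on the T+E2 array (y axis, log2 intensity), with dashed lines at 2-fold; grey points are measured genes and coloured points are the immediate early genes and the androgen response list, all drawn without the floor. Among genes measured on both arrays, Fos lies farthest above the diagonal at 8.30 and 13.38.

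Members of the androgen response list were on balance higher with T+E2. Of 57 measured members of the androgen response list, 7 were at least 2-fold higher, 1 was at least 2-fold lower and 49 lay between. Zbtb16 was higher by at least 3.87 (log2), Fkbp5 by 2.99, the zinc finger gene Zbtb10 by 1.22 and the kinase gene Sgk1 by 1.21. The list median was 0.40, at the 100th percentile of random lists matched on level and at 99.7 with matching on genomic span as well. Members of all pathway lists together, without the immediate early genes, also lay above matched random lists, with a median of 0.24. The percentile alone therefore does not set androgen targets apart from other pathway genes. With the span trend removed, Sgk1 stood at 0.79, under 2-fold. Higher members not named here are not given with that trend removed.

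In the estrogen response list, 8 of 27 measured members were at least 2-fold higher, none was at least 2-fold lower and 19 lay between. They included Fos (5.07), the early growth response gene Egr1 (2.02), Ier3 (1.57) and the insulin-like growth factor receptor gene Igf1r (1.36). The list median of 0.42 lay at percentile 99.8. Fos, Egr1 and Ier3 also belong to the immediate early genes, and without the shared members the median was 0.35, at percentile 98.0. Without a floor all 45 members on the array entered, including those near background on both arrays. The median was then 0.02, at percentile 82.6, and the list no longer stood apart. Igf1r stood at 0.77 with the span trend removed, and higher members not named here are not given that way.

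The receptors themselves differed little where they could be measured. Esr1, Esr2 and Pgr, the genes of the nuclear estrogen receptors and the progesterone receptor, lay below the floor on both arrays, so no difference is given for them. The membrane estrogen receptor gene Gper1 was at 7.93 in untreated cells and 8.11 with T+E2 (0.19), and the glucocorticoid receptor gene Nr3c1 at 11.34 and 11.31 (-0.03). Probe sets of both genes lay on opposite sides. Of 11 measured steroid receptor and cofactor genes, 1 was higher, 0 were lower and 10 lay between, with a median of 0.19 at percentile 73.2. At a floor of 4 the median was 0.50 at percentile 98.7, and the list stood apart. The member that was higher was the corepressor gene Nrip1 (1.03), which stood at 0.68 with the span trend removed. Of 10 measured steroid metabolism genes, 0 were higher, 1 was lower and 9 lay between, with a median of -0.03 at percentile 28.6. The lower member was the hydroxysteroid dehydrogenase gene Akr1c14 (-1.01).

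Immediate early genes, which are transcribed within minutes of a stimulus, were higher with T+E2 as a group. Of 27 measured members, 16 were at least 2-fold higher, 0 were lower and 11 lay between. Fos (5.07), Ier2 (4.25), Egr3 (at least 3.52) and Zfp36 (3.13) differed most. The list median was 1.18 (interquartile range 0.38 to 2.19), the highest of the 29 lists, at the 100th percentile under both matchings.

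Transcripts of signalling pathways that pattern the urogenital mesenchyme were on balance higher with T+E2 by modest amounts. Activity of the pathways was not measured. In the hedgehog pathway all 11 measured members lay above 0, and 3 were at least 2-fold higher, 0 lower and 8 between. Those 3 were the forkhead target gene Foxf2 (1.28), the transcription factor gene Gli3 (1.14) and Sufu (1.02), a negative regulator of the pathway. The median was 0.58 at percentile 99.8. In the FGF and growth factor list, 4 of 26 were higher, 1 was lower and 21 lay between, with a median of 0.47 at percentile 99.96. The FGF signalling inhibitor gene Spry4 (at least 2.04), Pdgfc (1.41), Nrg1 (1.36) and Igf2 (1.16) were higher. In the BMP and TGF-β list, 4 of 28 were higher, 0 were lower and 24 lay between, with a median of 0.39 at percentile 99.6. In this list 23 members lay above 0 and 5 below. Its higher members were Id4 (at least 1.36), the inhibitory Smad genes Smad6 (1.27) and Smad7 (1.04), and Tgfbr3 (1.26).

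Of 31 measured urogenital and mesenchymal transcription factors, 5 were higher, 0 were lower and 26 lay between, with a median of 0.39 at percentile 99.5. Gata6 (1.48), Runx1 (1.41), Gata4 (1.38) and Zeb2 (1.16) were among the higher ones. In the Wnt pathway 1 of 18 members was higher, 0 were lower and 17 lay between, with a median of 0.41 at percentile 99.2. The higher member was the nuclear effector gene Lef1 (at least 1.41). In the Notch pathway 1 of 10 was higher (Notch3, 1.09), 0 were lower and 9 lay between, with a median of 0.37 at percentile 93.7. Without a floor all 21 members on the array entered, including those near background on both arrays. The median was then 0.04 at percentile 98.8, where the list stood apart. In the angiogenesis and vessel guidance list 5 of 21 were higher, 0 were lower and 16 lay between, with a median of 0.61 at the 100th percentile. Flt1 (1.52), which encodes a VEGF receptor, Nrp2 (1.23), Vegfd (1.13) and Slit3 (1.06) were among them.

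The difference between the arrays grew with genomic span. With that trend removed, Gli3 stood at 0.56, Sufu at 0.66, Pdgfc at 0.91, Nrg1 at 0.53, Tgfbr3 at 0.75, Runx1 at 0.87, Zeb2 at 0.71, Nrp2 at 0.81 and Slit3 at 0.34, all under 2-fold. Smad6 (0.98), Smad7 (0.997) and Notch3 (0.92) came just under it, while Foxf2, Spry4, Igf2, Id4, Gata4, Gata6 and Flt1 stayed above it. Lef1 and Vegfd are not given with that trend removed. The hedgehog, Wnt and transcription factor lists no longer stood apart when the mean of all probe sets of a gene was used. That mean includes probe sets near background on both arrays, which draw differences toward 0. The Wnt list also did not stand apart without a floor, where members near background on both arrays entered.

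Genes of the extracellular matrix differed in both directions. Of 48 measured members, 4 were at least 2-fold higher, 2 were lower and 42 lay between, with a median of 0.34 at the 100th percentile and at 99.5 with span matched. The proteoglycan gene Lum (-1.81) and the elastin gene Eln (-1.79) were lower with T+E2, and the collagen genes Col12a1 (1.56) and Col5a3 (1.21) were higher. Among 23 smooth muscle and contractile genes, 4 were higher, 1 was lower and 18 lay between, with a median of 0.16 at percentile 86.4. The list stood apart with its mean in place of the median (0.37, percentile 99.8). It also did so without a floor, where members near background on both arrays entered (0.14, percentile 97.97). Itga8 (at least 1.93), Lmod1 (1.65) and Ldb3 (1.31) were higher, and Tagln, which encodes the actin-binding protein transgelin, was lower (-1.43). None of 21 matrix proteases and inhibitors was 2-fold different, and their median was 0.07 at percentile 62.3. The largest were Adamts12 (0.82) and Adamts1 (0.79).

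Interferon response genes had a median of 0.35 at percentile 98.0, with 2 of 28 members higher, 1 lower and 25 between. Oasl2 (at least 2.23) and the guanylate-binding protein gene Gbp7 (1.57) were higher and Ifi47 was lower (-1.23). With the list mean in place of the median the percentile was 96.5, within the range of random lists. Of 21 chemokine and inflammatory cytokine genes, 2 were higher, 1 was lower and 18 lay between, with a median of 0.11 at percentile 54.6. Lcn2 and the interleukin-1 receptor antagonist gene Il1rn (1.95) were higher and Cxcl15 was lower (-2.57 against the floor). With the mean of all probe sets of a gene this list's median was -0.37 at percentile 0.63, so its direction turned and it stood apart on the low side.

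Proliferation genes showed no 2-fold difference. None of 61 measured cell cycle genes passed it, with a median of 0.20 at percentile 92.0. The replication licensing inhibitor gene Gmnn (-0.97) and the proliferation marker Mki67 (0.89) differed most. The list stood apart with span matched as well (percentile 99.8) and with the mean of all probe sets (0.17, percentile 98.01). Of 24 cell cycle inhibitors and p53 targets, Btg2 (2.60) was higher, 0 were lower and 23 lay between. Their median was -0.04 at percentile 18.03, and their mean, 0.09, had the opposite sign.

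Lipid genes did not reach 2-fold either. The 32 cholesterol and fatty acid synthesis genes had a median of 0.07 at percentile 60.7, with Fasn at 0.87 and Acaca at 0.83. The 11 adipocyte genes had a median of 0.21 at percentile 77.7, with Pnpla2 at 0.90 and Lpl at -0.86. In the hypoxia and glycolysis list, 3 of 29 were higher, 0 were lower and 26 lay between, with a median of 0.10 at percentile 67.9. These 3 were the hypoxia-inducible factor gene Epas1 (2.35) and the hexokinase genes Hk2 (1.20) and Hk1 (1.04), the last at 0.63 with the span trend removed.

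Among stress lists, Ppp1r15a (at least 2.31) was the only one of 32 unfolded protein and amino acid stress genes that was higher, with 0 lower, 31 between and a median of 0.07 at percentile 59.6. Of 16 heat shock genes, Hspb1 (2.47) and Hspa4l (1.01) were higher, 0 were lower and 14 lay between, with a median of 0.08 at percentile 60.5. Hspa4l stood at 0.81 with the span trend removed. Of 25 oxidative stress genes, the glutathione transferase gene Gsta3 (1.63) was higher, its relative Gsta4 was lower (-1.66 against the floor, so at least that far) and 23 lay between. The median of 0.19 lay at percentile 90.6, and at 99.5 with span matched.

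Oxidative phosphorylation was the only list that stood apart on the low side. None of its 39 measured members reached 2-fold, but 36 lay below 0, with a median of -0.26 at percentile 0.0 and at 1.77 with span matched. Its members Uqcrq (-0.88) and Atp5j (-0.66) were lowest. The 25 ribosomal protein genes had a median of -0.08 at percentile 8.80, with none at 2-fold and Rps25 (-0.92) and Rps27 (-0.57) farthest from 0. The 21 housekeeping genes had a median of -0.01 at percentile 39.6, with none at 2-fold, Chmp2a at -0.90 and Polr2a at 0.82.

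Of the 29 lists, 11 stood apart on the high side and 1 on the low side. With genomic span matched as well, 13 and 1 did, including the same 12 lists. The 588 measured members of all pathway lists together, without the immediate early genes, had a median of 0.24, against 0.01 to 0.10 for the central range of random lists matched on level and span. The percentiles of single pathway lists do not take out this general shift.

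**Figure D2:**
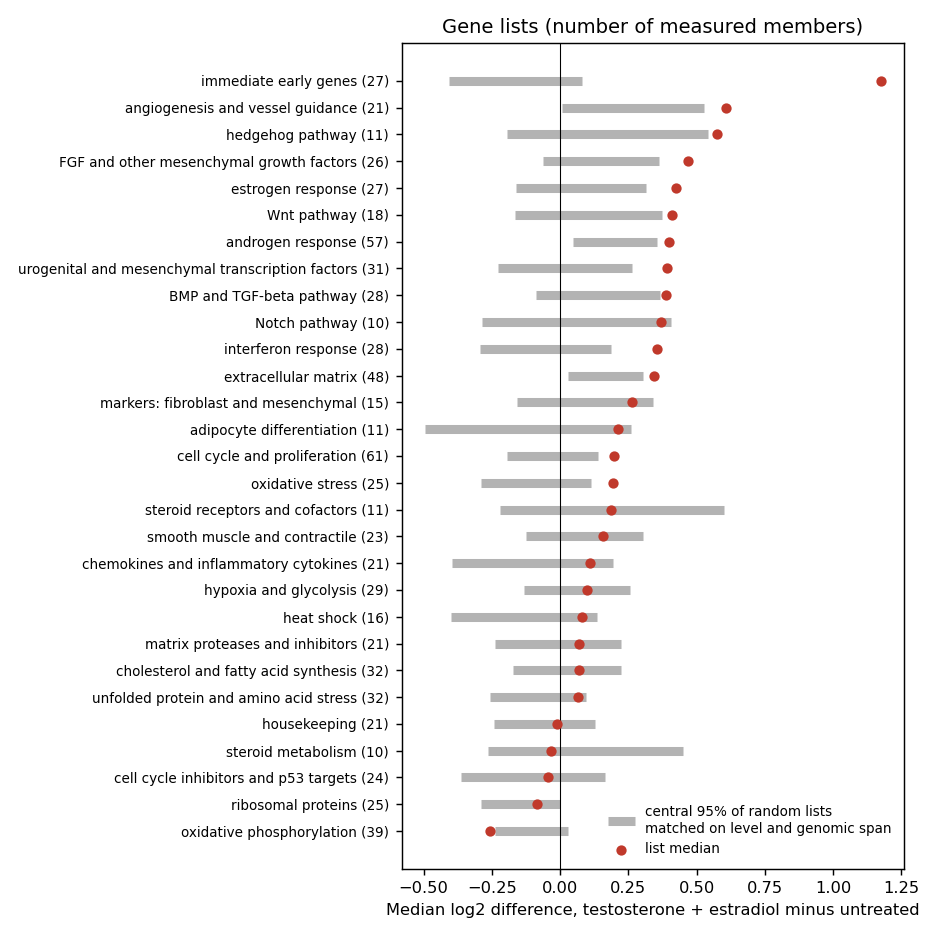
Median log2 difference (x axis, T+E2 minus untreated) of each gene list with its number of measured members; grey bars give the central range of random lists matched on level and genomic span. The immediate early genes lie farthest right at 1.18 and oxidative phosphorylation farthest left at -0.26.

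Markers of other cell types were mostly under the floor. Of 22 named epithelial markers 3 were measured. The E-cadherin gene Cdh1 was 4.59-fold higher with T+E2, from 5.37 (log2), near the floor, in untreated cells to 7.57. The other 2 lay between and are named after their values were seen. Esrp2 was well above the floor on both arrays (11.9 in untreated cells and 12.5 with T+E2), and Trp63 was at 7.99 and 8.46. Of 15 endothelial markers 4 were measured, of which Flt1 was higher, 0 were lower and 3 lay between. Of 19 leukocyte and macrophage markers 3 were measured, and Lyz2 was lower (-1.53), with 2 between. Of 12 neural and Schwann cell markers 3 were measured and none reached 2-fold, with Ncam1 at 0.94. Of 20 skeletal muscle markers 2 were measured, Pax3 and Tnnc1, neither at 2-fold. Of 15 cartilage and bone markers 4 were measured, and Phex was higher (1.26), with 3 between. None of 10 mesothelial or 5 erythroid markers was measured. Of 16 fibroblast and mesenchymal markers 15 were measured, with the ecto-nucleotidase gene Nt5e higher (at least 1.28), Lum lower and 13 between. Their median was 0.26 at percentile 97.49, just within the range of random lists. At a floor of 6 (percentile 97.75) and with loess on level (percentile 99.2) the list stood apart.

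The difference between the arrays followed the genomic span of the gene. Among 9980 protein-coding genes, the difference and the span correlated across genes with a Spearman rho of 0.384, and genes are not independent replicates. In the 998 genes with the shortest spans (median 3.25 kb) the median difference was -0.18, with 20 genes at least 2-fold higher and 79 lower. In the 998 with the longest spans (median 194 kb) it was 0.56, with 183 higher and 9 lower.

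**Figure D3:**
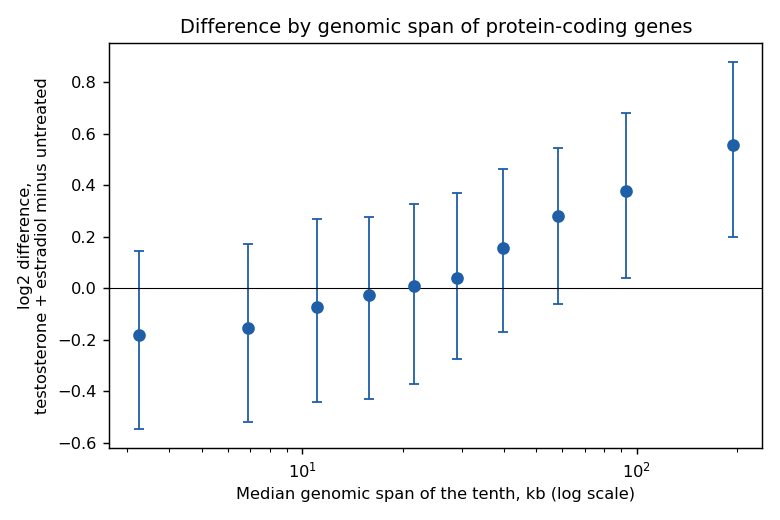
Median log2 difference (y axis, T+E2 minus untreated) of protein-coding genes in groups of equal size ordered by genomic span (x axis, kb, log scale), with bars from the lower to the upper quartile. The medians go from -0.18 in the shortest group to 0.56 in the longest.

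RNA classes differed as well. Of 227 measured long non-coding RNAs, 6 were at least 2-fold higher and 67 at least 2-fold lower, with a median of -0.51, against 499 higher and 338 lower of 9980 protein-coding genes. The control probe sets for 18S ribosomal RNA were lower with T+E2 (-1.16, -1.58 and -0.62). The 3′ to 5′ intensity ratio was 2.96 in untreated and 2.83 in T+E2 cells for Actb, and 2.28 and 2.17 for Gapdh. For 18S ribosomal RNA it was 0.33 in untreated and 0.442 in T+E2 cells, the opposite direction and the largest shift of the 3.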

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

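All tests in this part were chosen after the result they bear on had been seen. Probe sets that the annotation does not list enter no gene count above. Of 1685 measured ones, 103 were at least 2-fold higher on the T+E2 array than on the untreated control array, which is why they are given here, and 477 were at least 2-fold lower, with a median difference of -0.21.

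The immediate early genes were higher with T+E2, with a list median of 1.18. A trend with level and genomic span is argued against as the whole account, because the median of 1.18 lay far above the upper bound of 0.08 for random lists matched on both. A brief stimulus shortly before harvest, such as handling of the flasks, may also raise these genes, and should then leave genes induced hours later near the random range and less often at 2-fold. Delayed growth response genes had a median of 0.42, above the upper bound of 0.29, while 2 of 25 were at least 2-fold higher against 16 of 27 immediate early genes, so the outcome went both ways. Handling, cell density (on which the labels conflict) and the hormones cannot be told apart here, because each condition is 1 array.

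The difference grew with genomic span. Dependence on level is argued against, since the gap between the longest and shortest genes was 0.68, 0.88 and 0.65 within low, middle and high levels, with a lowest bootstrap bound of 0.57. More degraded RNA on the untreated array would raise its 3′ to 5′ ratios. The larger excess, over Actb and Gapdh, was 0.076 on the log2 scale, so these ratios showed little difference. The criterion could count against degradation only with ratios clearly lower on the untreated array, so near-equal ratios could not decide it. For 18S ribosomal RNA the ratio was lower on the untreated array (0.33 against 0.442). Transcript length was not analysed here, and a hormone effect on long genes was not tested.

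Long non-coding RNAs were lower with T+E2, with a median of -0.51. Their short spans and low levels are argued against as the whole account, because -0.51 lay below the lower bound of -0.11 for matched random lists. More unspliced RNA or genomic DNA on the untreated array may contribute: minor probe sets of protein-coding genes, at least 5 log2 units under the main one, had a median of 0.13, just below the lower bound of 0.16 for level-matched main probe sets. That margin is small beside -0.51, the median is above 0, and 662 of 1006 minor probe sets could be matched. Genomic span, which the difference follows, was not matched in this comparison. Of these 662, 97 were at least 2-fold higher and 122 at least 2-fold lower. Among the 9980 main probe sets, not matched on level, 499 were higher and 338 lower. A hormone effect on these RNAs stays open and untested.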

How the results depend on the processing

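The alternatives of loess on genomic span, protein-coding genes alone, span matching and lists without immediate early members were chosen after seeing the data. No paired analysis was possible because both titles carry replicate number 1 and each group holds 1 array, and for the same reason no array could be left out. Against 509 higher genes, the count was 315 with the mean of all probe sets, 1759 at 1.5-fold, 96 at 3-fold, 84 where every one of 2 or more probe sets had to pass, and 303 with loess on genomic span; other settings gave 390 to 638. Against 412 lower genes, it was 1452 at 1.5-fold, 77 at 3-fold and 37 where every probe set had to pass; other settings gave 338 to 520. The share of calls that were higher was 55.3% as deposited and 52.4% (485 higher, 441 lower) with a second quantile normalization. It was 44.0% (408 and 520) after median centring. With loess on level it was 43.0% (390 and 518), and with loess on span 41.2% (303 and 433). With the mean of all probe sets it was 44.1% (315 and 400), and with every probe set passing 69.4% (84 and 37). Which direction holds more genes thus depends on the scaling and on the rule for the gene value. Of the 509 and 412 genes, 258 and 308 were called with loess on span and 223 and 269 with the mean of all probe sets. Probe sets of a gene lay on the same side in 71.6% of genes at a floor of 6 and 67.7% at a floor of 4. Across 9 alternatives 11 to 14 lists stood apart, and androgen response, FGF, BMP and TGF-β, extracellular matrix, immediate early genes, angiogenesis and oxidative phosphorylation did so in every one. Without a floor the epithelial markers also stood apart, but only 3 of 22 were measured, so that median rests mostly on values under the floor. The estrogen, Wnt, smooth muscle and Notch medians without a floor rest partly on such values. No named gene at 2-fold changed sign in any alternative run for it, and among the other named genes Nr3c1 did, from -0.03 to 0.08 with the mean of all probe sets; of those at 2-fold, 6 of 82 came under it after median centring, 21 of 64 with the mean of all probe sets and 19 of 82 with loess on span. The mean of all probe sets averages in probe sets near background on both arrays, such as a Gli3 probe set at 2.135 (untreated) and 2.146 (T+E2). This draws differences toward 0 and takes genes under the floor, with 81 of 102 named genes still measured. Other causes of these shifts were not tested. Of all probe sets, 50.3% on the untreated and 52.0% on the T+E2 array lay under an intensity of 8, which limits what can be seen below the floor.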

Other observations

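Of 227 measured long non-coding RNAs, 67 were at least 2-fold lower with T+E2, 6 were at least 2-fold higher and the rest lay between. Neat1 and Malat1 are given as examples chosen after their values were seen. Neat1, which scaffolds paraspeckles, was at 13.22 in untreated cells and 11.48 with T+E2 (-1.74), and Malat1, a nuclear speckle RNA, was at 14.19 and 12.99 (-1.20). Others did not share this direction or size: Tug1 stood at 0.30, Kantr (with probe sets on opposite sides) at 0.26 and Jpx at -0.09, also chosen after their values were seen.

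The test here was chosen after the values of Fkbp5, Zbtb16 and Fam107a had been seen. All 3 are also known to respond to corticosteroids, and Nr3c1 was measured on both arrays, so a response shared with corticosteroids may contribute to their difference. Other corticosteroid-responsive genes whose values had not been read singly (17 measured) had a median of 0.25, under the upper bound of 0.27 for random lists matched on level and span and above the random median of 0.00. Several of these, such as Klf15, Cebpb, Timp3 and Lox, had entered the medians of lists given above, so they are not independent of what had been seen. The full list of 27 measured members had a median of 0.28, above its upper bound of 0.20 (percentile 99.5), with 4 at least 2-fold higher, but some of its values had been seen when it was written. Members of all pathway lists together, without the immediate early genes, had a median of 0.24 under the same matching. A median of this size is therefore not particular to corticosteroid-responsive genes. The hypothesis is therefore left open.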
